A study of Mus musculus with 3 samples.

How the data were processed

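Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the transcription factor c-FOS on DNA of ASZ001, an established mouse basal cell carcinoma cell line. The series holds 3 samples taken 6 days after induction: 2 c-FOS ChIP samples and 1 input, which is chromatin that was not immunoprecipitated. Groups were taken from the sample titles.

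The authors aligned the reads with Bowtie2 to mm9 and called peaks with MACS2, per the submitters' processing notes. Tool versions, the peak threshold, the use of the input and the way the 2 ChIP samples were combined are not given in the sources used here. The values used are the chromosome, start and end of each peak as the authors deposited them, in 1 list that names no replicate. Fold enrichment, height, score and p-value per peak were not analysed here, so peak strength was not compared. Read totals were not used here either, so the depth is unknown, and the sensitivity of the list cannot be set against sequencing depth. All values therefore describe 1 peak list with no measure of the spread between the 2 ChIP samples.

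The build was checked against the chromosome lengths of mm9 and mm10 held in GenomeInfoDb 1.38.1 (R 4.3.3). No peak lay beyond an mm9 chromosome end, while 55 peaks on 5 chromosomes lay beyond the mm10 ends. Coordinates are printed 1-based on mm9. The gene table at hand was for GRCm38 (the assembly also called mm10), so its coordinates were not joined to the peaks. From that table only the number of protein-coding genes named on each chromosome was used (21631 on chromosomes 1 to 19 and X). An mm9 genome sequence and gene annotation were not used here. For that reason the planned analyses of sequence motifs, of genomic features and of gene lists were not run, and no peak was assigned to a gene.

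Peak widths and the gaps between neighbouring peaks were computed from the coordinates with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The number of peaks on each of 21 chromosomes was compared with its share of mm9 length by a two-sided exact binomial test with Benjamini-Hochberg adjustment and a threshold of 0.05. The whole assembled length was used, gaps included, in place of the mappable length that had been planned. The binomial test treats peaks as independent. A two-sided permutation test over 522 whole windows of 5 Mb, with 100000 resamples of the windows' chromosome labels, was therefore added after the data were seen. The 95% intervals of chromosome densities come from 2000 bootstrap draws of these windows, and they cover variation along a chromosome but not between samples. The piece of each chromosome beyond its last whole window enters neither the permutation nor these intervals, nor the intervals of peaks per gene derived from them. Clustering was tested by 1000 random placements of the same peak widths within each chromosome, one-sided. Placement was uniform over the assembled length, gaps included, and took no account of mappability. Shares of peaks carry Wilson 95% intervals, which cover counting error only and treat peaks as independent.

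Both tests were checked on 20 simulated lists of each kind, with 15011 peaks each. In lists where chromosome 11 had been given a density ratio of 2 and chromosome 14 a ratio of 0.5, the mean recovered ratios were 2.03 and 0.497 and both chromosomes were found every time by either test. In lists with clustered peaks and no difference between chromosomes, the binomial test called a mean of 10.3 of 21 chromosomes and the window permutation a mean of 0.15. The simulated clusters were shorter than a window, so this check does not cover longer runs of dense or empty sequence. In a list with 1500 peaks in planted close pairs, an excess of 1475 peaks with a neighbour within 1 kb was recovered.

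The named items follow a rule written before the data were examined: with no usable annotation and no score, the 10 widest peaks and the 5 windows of 1 Mb with the most peaks. A tie in the fifth place brought in 1 further window. The alternatives were the peaks wider than the median, merging of peaks within 1000 bp or 10 kb, chromosomes 1 to 19 and X alone, and, added later, the window permutation and placements restricted to each peak's own 1 Mb window or to the span between the first and last peak. Leaving out a replicate was not possible with 1 list. Figures were drawn with matplotlib 3.10.9.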

Results

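The experiment mapped where c-FOS, a subunit of the transcription factor AP-1, bound the genome of ASZ001 cells during an experimentally induced transition from basal cell to squamous cell carcinoma. ASZ001 is a mouse basal cell carcinoma line. The cells carried RasV12, an activated form of the signalling protein Ras, together with an shRNA against the TGF-beta receptor TGFbR1, and were treated with Dox and 4OHT. Chromatin was collected on day 6 after induction. The c-FOS antibody was applied to 2 samples, and 1 input sample had no antibody. All 3 samples shared the same genotype and treatment, so the design implies a comparison of c-FOS ChIP with input, which enters here only as far as it shaped the peak list. It holds no uninduced arm, and a change in binding on induction was not analysed here. The depth behind each peak is unknown, and no value below has a replicate error.

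The list held 15011 c-FOS peaks spread over 21 chromosomes, 1 to 19, X and Y. Together they covered 2.84 Mb, or 0.107% of mm9, at a mean density of 5.65 peaks per Mb. Peaks were narrow, with a median width of 158 bp (bootstrap 95% interval 157 to 160) and quartiles of 119 and 225 bp. The narrowest peaks measured 98 bp. This was also the commonest width, shared by 1613 peaks or 10.7% of the list (Wilson 95% interval 10.3 to 11.3%), whereas the next commonest width of 123 bp was shared by 120 peaks. Only 263 peaks, 1.75% of the list, were wider than 500 bp. No peaks overlapped, and the smallest gap between neighbours was 76 bp. The lowest width and the smallest gap may both be set by the peak caller, whose settings are not given, and were not tested as properties of binding.

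Listed peaks were distributed very unevenly among chromosomes. Counts were set against assembled length, with no correction for copy number or mappability, so the spread is a property of the list. Chromosome 11 held the most, with 1833 peaks or 15.0 per Mb (bootstrap 95% interval 9.81 to 20.5), 2.66 times the genome-wide density. Chromosome 19 followed at 13.2 per Mb (7.88 to 19.8), chromosome 5 at 10.7 per Mb (7.46 to 14.6) and chromosome 8 at 10.7 per Mb (7.22 to 14.4). Chromosomes 5, 8 and 11 together carried 32.4% of the peaks on 15.3% of the genome length. At the other end, chromosome 12 held 147 peaks or 1.21 per Mb (0.800 to 1.70), and chromosome 14 held 109 peaks or 0.871 per Mb (0.552 to 1.22). Among the 19 autosomes the densest exceeded the sparsest 17.3-fold, and 11.2-fold when peaks within 10 kb were merged.

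Few listed peaks lay on the sex chromosomes. Chromosome X carried 34 peaks over 167 Mb, or 0.204 per Mb (bootstrap 95% interval 0.0606 to 0.285), 0.0361 times the genome-wide density. Of these, 2 lay before and 32 after a stretch of 54.0 Mb with no peak (39278184 to 93291259). The distal tip of the chromosome, from 166000001 onward, held 8 of the 34. This region was chosen after its count was seen, and the end of mouse chromosome X is known to carry the pseudoautosomal region shared with Y. These 8 peaks lay beyond the 33 whole windows of 5 Mb on X. The interval above and the window permutation below leave them out, so the interval describes the rest of the chromosome. Chromosome Y carried 3 peaks, at 2779686 to 2780008, 2859003 to 2859160 and 2891868 to 2892090. With 3 whole windows of 5 Mb, Y did not pass the window permutation (adjusted permutation p = 0.192). The lengths of Y and X were both counted with assembly gaps included. Y had so few peaks and whole windows that its low count is not a like result to that of X. None of the peaks was listed on the mitochondrial genome or on unplaced sequence.

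By the exact binomial test, which treats peaks as independent, 19 of 21 chromosomes departed from their share of genome length after Benjamini-Hochberg adjustment, 8 above and 11 below it. When windows of 5 Mb were permuted in place of single peaks, 7 chromosomes passed. Chromosomes 11 (adjusted permutation p = 0.00021), 5 (0.00301), 8 (0.00515) and 19 (0.00858) were denser than the genome, and chromosomes X (0.000945), 14 (0.00858) and 12 (0.0137) were sparser. The p-value for chromosome 11 before adjustment, 1e-05, was the smallest that the permutations can give. The 24 whole windows of chromosome 11 end before position 120000001, so the peaks beyond it were not counted in this test. Chromosome 9 (2.74 peaks per Mb, adjusted permutation p = 0.0947) and chromosome 10 (2.88 peaks per Mb, adjusted permutation p = 0.0667) did not pass the window test.

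**Figure D1:**
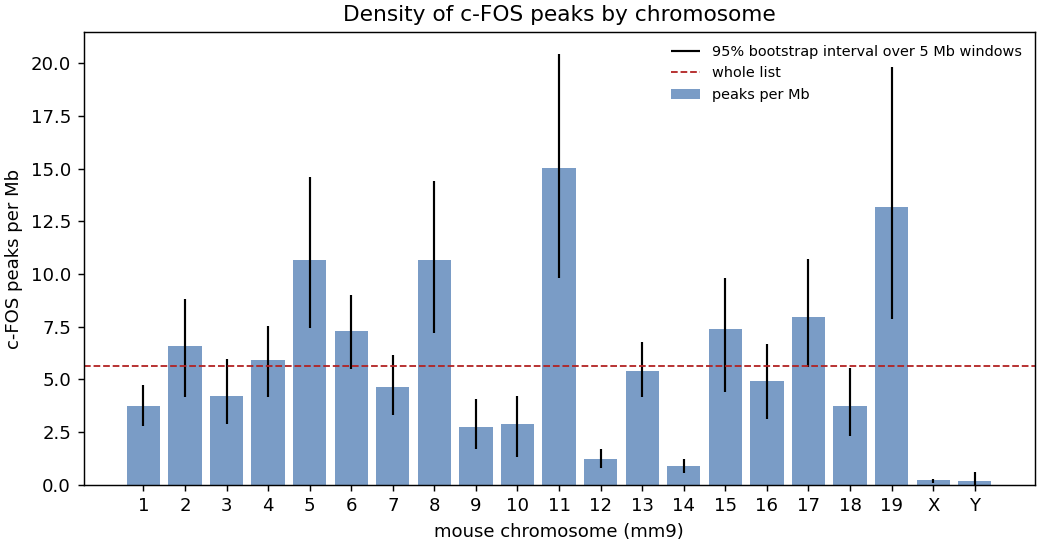
Density of c-FOS peaks (peaks per Mb, vertical axis) on each mouse chromosome of mm9 (horizontal axis). Bars give the density, black lines the bootstrap 95% interval over whole 5 Mb windows (chromosome ends beyond the last one left out), and the dashed line the density of 5.65 per Mb over the whole list. Chromosome 11 stands at 15.0 per Mb and chromosome 14 at 0.871.

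Within chromosomes, c-FOS peaks gathered in a limited set of regions. Of 2649 windows of 1 Mb on chromosomes 1 to 19 and X, 876 (33.1%) held no peak, while random placement of the same peaks within their chromosomes left a mean of 255 and at most 283 windows empty. Unsequenced windows can hold no listed peak, yet they were open to random placement. The 265 densest windows, 10% of all, held 7400 peaks or 49.3% of those on these chromosomes. They were picked by their counts and no random share was computed, so differences between chromosomes also enter this share. In 60 windows the count was above 33, the highest reached in any window of the 1000 random placements. The longest stretch without a peak on an autosome measured 14.2 Mb and lay on chromosome 14 (87816460 to 102053072). With each autosome ranked by its longest such stretch, chromosome 12 came next at 10.7 Mb (41750657 to 52478483).

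Counting peaks as listed, the window with the most peaks was on chromosome 19 from 5000001 to 6000000, with 94 peaks, 16.6 times the genome-wide mean. Its peaks had a median width of 168 bp. Distal chromosome 11 contributed 3 further windows. The window from 117000001 to 118000000 held 86 peaks, that from 115000001 to 116000000 held 75, and that from 120000001 to 121000000 held 69. Merging peaks within 1000 bp changed this order: it left 59 regions in the chromosome 19 window, against 73, 60 and 51 in those of chromosome 11. The fifth place among unmerged windows was shared by chromosome 2 from 167000001 to 168000000 and chromosome 8 from 73000001 to 74000000, each with 66 peaks. On chromosome 2 this was against a mean of 6.58 peaks per Mb for the whole chromosome. The counts in these windows lay between 11.7 and 16.6 times the genome-wide mean.

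**Figure D2:**
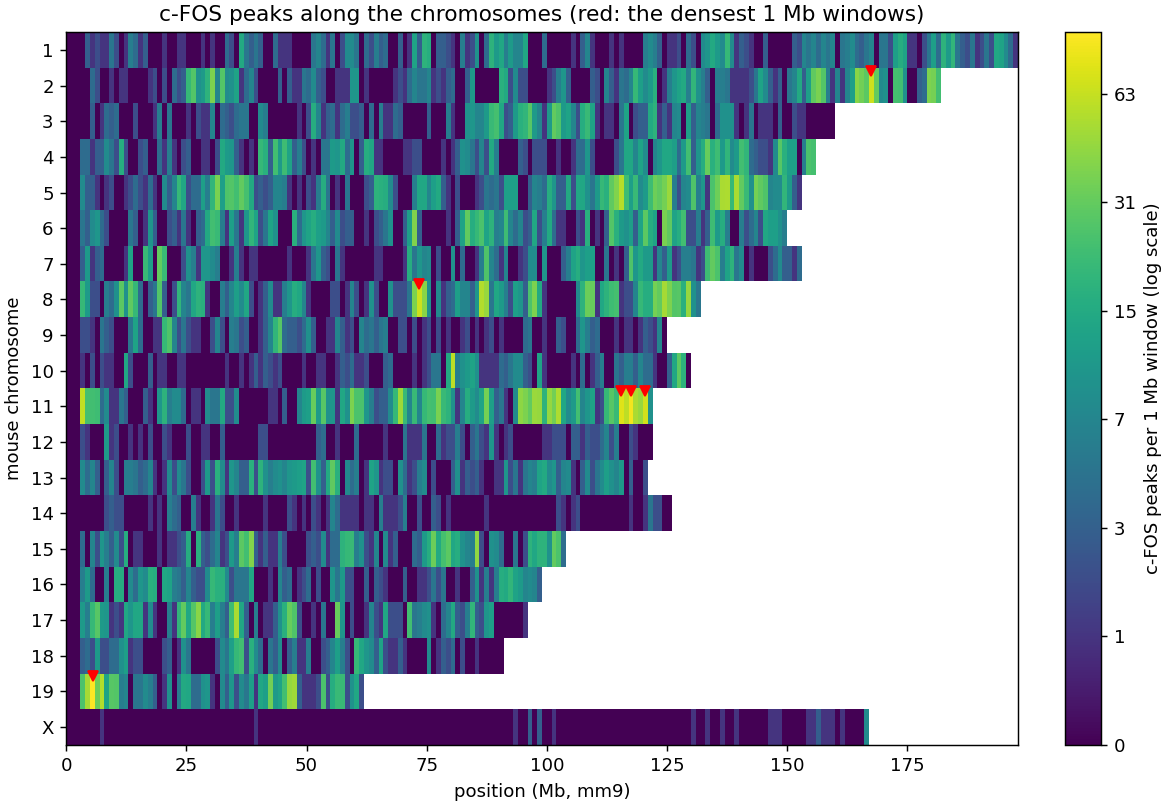
Number of c-FOS peaks per 1 Mb window (colour, log scale) along chromosomes 1 to 19 and X (rows) by position in Mb of mm9 (horizontal axis). Red triangles mark the densest windows, led by chromosome 19 with 94 unmerged peaks (59 regions after merging within 1000 bp, against 73 on chromosome 11 from 117000001), and the row of chromosome X is almost empty.

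Neighbouring peaks lay closer together than random placement over the assembled length gave. That placement ignored assembly gaps and mappability, so the test cannot say whether the clustering is particular to c-FOS. The median gap between neighbours was 30.5 kb, against a mean of 92.4 kb over 1000 random placements (range 89.4 to 94.6 kb; one-sided permutation p = 0.000999, the smallest that these placements can give). A neighbour within 1 kb was found for 3731 peaks, or 24.9% (Wilson 95% interval 24.2 to 25.6%), where random placement gave a mean of 287 peaks or 1.91%. The Wilson interval treats peaks as independent, although both peaks of a close pair count together, so it is likely too narrow. Within 10 kb the observed share was 48.7% and the random share 15.0%. Both counts were above the highest of the random placements, 353 and 2426 peaks. Placing each peak at random within its own 1 Mb window reduced the 13.0-fold excess of neighbours within 1 kb to 5.49-fold. Within 10 kb it raised the random share to 29.8%, and the excess went from 3.25-fold to 1.63-fold.

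Peaks linked by gaps of at most 1 kb formed 1361 pairs and 292 groups of 3 or more. The largest group was on chromosome 8, from 86721266 to 86727770, where 10 peaks lay within 6505 bp. Groups of 9 peaks were found on chromosome 11 from 3032035 to 3037337 and on chromosome 19 from 46574133 to 46578943. The distances between neighbouring peaks thus spanned a range from 76 bp to the 54.0 Mb on chromosome X.

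**Figure D3:**
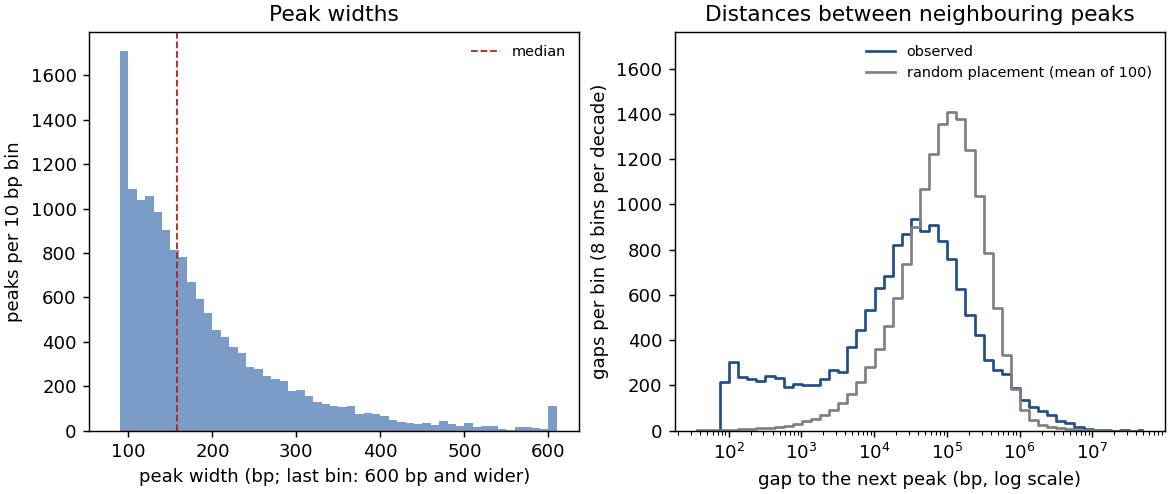
Left, number of peaks (vertical axis) by peak width in bp (horizontal axis, the last bin holding peaks of 600 bp and wider), with the median of 158 bp dashed. Right, number of gaps (vertical axis) by distance to the next peak in bp (horizontal axis, log scale), observed and as the mean of 100 random placements; the observed line has a shoulder of gaps below 1 kb that the random line lacks.

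The 10 widest peaks were spread over 6 chromosomes, and 5 of them were on chromosome 5. The widest, on chromosome 17 from 39980590 to 39983318, measured 2729 bp, 1.90 times the next. The others on the list ranged from 1438 bp down to 1011 bp. Those on chromosome 5 started at 143578204 (1438 bp), 115939245 (1288 bp), 113566962 (1180 bp), 32437267 (1068 bp) and 125869462 (1011 bp). The remaining 4 were on chromosome 15 from 85501674 to 85502794 (1121 bp), chromosome 6 from 47403735 to 47404849 (1115 bp), chromosome 11 from 100116343 to 100117398 (1056 bp) and chromosome 3 from 96132008 to 96133044 (1037 bp). Merging peaks within 1000 bp widened 5 of the 10 by more than 1.5 times: the region on chromosome 17 then measured 5788 bp, that on chromosome 15 4453 bp, those holding the chromosome 5 peaks at 143578204 and 32437267 measured 3762 and 2841 bp, and that on chromosome 11 1665 bp. Among the merged regions that hold these 10 peaks, the one on chromosome 17 was 1.30 times the next, which was then the one on chromosome 15. Each of the 10 had at least 1 other peak within 10 kb, and the peak on chromosome 5 at 143578204 had 11. Which genes these regions contain was not analysed here, because no annotation of mm9 was used. No filter for regions prone to artefact signal was applied here. Neither these peaks nor the groups of close peaks above were therefore checked as sites of c-FOS binding.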

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

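The list can be judged only by its intervals: without scores, depths or separate replicates, neither a stricter peak threshold nor leaving out a replicate could be tried, and width stood in for strength. Width had a floor of 98 bp that the caller may have set, so it is a weak stand-in. Keeping peaks wider than the median left 7501 of 15011 peaks by construction, merging peaks within 1000 bp left 12933, and keeping chromosomes 1 to 19 and X left 15008. The number of chromosomes past the threshold went from 19 by the binomial test to 7 by the permutation over 5 Mb windows, which was chosen after seeing the data; 12 chromosomes lost their call, and the simulated clustered lists show that the binomial test overcalls where peaks cluster. Chromosome 13, not called in either case, turned from 0.957 to 1.02 times the genome-wide density when peaks within 10 kb were merged; the cause was not tested. Under that merging 18 of 21 chromosomes kept both direction and side of the threshold, as did 20 among the wider peaks; chromosome 16 lost its call in both and chromosome 4 gained one after merging. Clustering kept its direction and its permutation p of 0.000999 in each alternative run: the median gap was 0.330 times the random mean in the full list, 0.350 in the wider peaks, 0.387 after merging within 1000 bp, 0.341 with placement between the first and last peak, and 0.670 with placement in each peak's own 1 Mb window. The alternatives planned for motifs, genomic features, gene lists and peak strength were not run, since they need an mm9 sequence, an mm9 annotation or a score.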

Other observations

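The tests of gene number, local clusters and chromosome copy number were chosen after the results had been seen. Both predictions for close neighbours were recorded as written before, although the placement within each peak's own 1 Mb window was not in the plan and was added later. Across chromosomes 1 to 19 and X, c-FOS peak density followed the density of protein-coding genes in part. Pearson's r was 0.617 (permutation p = 0.00374, adjusted 0.00748) and Spearman's rho 0.641 (p = 0.00274, adjusted 0.00548), with 20 chromosomes and 2 relations tested, and r was 0.646 without the 2 chromosomes farthest from the median gene density. Per protein-coding gene named in GRCm38, the list held 0.694 peaks on these chromosomes together, 1.35 on chromosome 8, 1.28 on chromosome 5, 1.15 on chromosome 19 and 1.14 on chromosome 11. The gene-rich chromosome 7 held only 0.349 peaks per gene, chromosome 9 0.283, chromosome 12 0.217, chromosome 14 0.128 and chromosome X 0.0352.

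For the uneven spread over chromosomes, the number of genes is argued against as the whole explanation for the sparsest chromosomes: on 4 chromosomes (9, 12, 14 and X) the 95% interval of peaks per gene lay wholly below the value for all of them divided by 1.5. By this margin, chosen after the results were seen, it holds on the sparse side alone: on 0 chromosomes did the interval lie wholly above 1.5 times that value. The intervals of the ratio were 1.31 to 2.63 on chromosome 8, 1.29 to 2.53 on chromosome 5, 1.07 to 2.23 on chromosome 11 and 0.988 to 2.49 on chromosome 19. Those of chromosomes 8, 5 and 11, and of chromosome 6 (1.055 to 1.726), lay above 1. All these intervals are those of peaks per Mb rescaled with gene counts held fixed, and they were not adjusted for the number of chromosomes. Chromosome 6 did not pass the window permutation (adjusted permutation p = 0.332). Whether peaks on the dense chromosomes were proportional to gene number is therefore not decided, and gene number stays open there. On the sparse side, chromosome 7 (0.357 to 0.669) narrowly missed the margin. Clusters shorter than 5 Mb are argued against as the whole explanation for the 7 chromosomes that passed when such windows were permuted (5, 8, 11, 12, 14, 19 and X). For the 12 others that passed the binomial test alone they stay open. Runs of dense or empty sequence longer than a window are not covered, since the permutation treats neighbouring windows as independent. Chromosomes X, 14 and 12 held empty stretches of 54.0, 14.2 and 10.7 Mb. A further candidate explanation that stays open is the copy number of whole chromosomes in this cell line, because more copies give more reads over each site. It predicts wider peaks on denser chromosomes, and the relation did not pass the test (Spearman's rho 0.313, p = 0.176, adjusted 0.176; Pearson's r 0.377, p = 0.0987, and 0.381 without the 2 farthest chromosomes). The prediction was not a sharp one, since more reads could also bring more narrow peaks into the list, so the test decides nothing about copy number. Read coverage of the input would decide it. An effect of the induction or of the genotype could not be tested, since all samples shared one condition.

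For the close neighbours, the density of peaks at the scale of 1 Mb windows is argued against as the whole explanation. The 3731 peaks with a neighbour within 1 kb were 4.74 times the highest number from 1000 placements within each peak's own 1 Mb window. Density that varies within such a window was not covered by these placements and stays open. Wide sites that the caller broke at short dips, and stronger binding in regions with several sites, stay open. Peaks with a close neighbour had a median width of 167 bp against 156 bp for the rest, a difference of 11 bp that passed the test written beforehand for broken sites (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). That test treats peaks as independent although they cluster, and its prediction was not a sharp one, since the pieces of a broken site are shorter than the site. The difference held on 12 of the 18 autosomes with at least 10 such peaks and was reversed on 5 (two-sided exact sign test over chromosomes, p = 0.143, added after the widths were seen). The list holds no score that would separate these explanations.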
